A study of Rattus with 27 samples.

How the data were processed

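Total RNA had been extracted with a Qiagen kit from the brain, the white blood cells and the spleen of each rat, reverse transcribed with M-MLV enzyme, amplified, labelled with biotin and hybridized to Affymetrix rat Gene arrays. The deposited table held 27596 probe values for each of 27 arrays. Per the labels, the authors processed the intensities with RMA, which corrects background, normalizes between arrays and summarizes probes, in an unstated version; whether the tissues were normalized together is not stated either. The labels give no scale. The deposited values are taken to be log2 intensities, since they ran from 1.53 to 13.49 with array medians between 4.96 and 5.31 and a like spread in every array. No further normalization was applied before the tests. No genome build goes with the probe table that was used, so genes are given by symbol and, for lead genes, by probe, without positions.

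Groups were taken from the sample titles: tissue, then sham, model or vehicle, then the replicate number, with 3 arrays per group. The numbers are 3, 4 and 5 in sham, 1, 2 and 3 in model and 2, 4 and 5 in vehicle, and a number shared by groups is not the same rat. Within a group the number is taken to link the 3 tissues of a rat. Residuals of the same rat in different tissues correlated with r between -0.058 and 0.517 across genes, 15 of 27 pairs above 0.1. In the vehicle group the pairs with brain lay between -0.058 and 0.032. Correlations between different rats across tissues were not computed, so the values cannot settle the link, which rests on the titles. The sample titles name a model group and the treatment protocol a YJ group at 25 mg/kg in its place, and no label links them, so no group is called treated. The description codes begin with S for sham, M for model and D for vehicle samples, and those with D are also written in another form; what D stands for is not stated, and it leaves open whether the vehicle-labelled group was the one given YJ. No label gives a hybridization date or batch, so a batch that coincides with a group cannot be separated from it.

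The probe table listed a gene for 15633 probes. Those with 1 symbol (15310) were kept and those with several (323) or without a listed gene (11963) left out, since no single gene can be named for them. Entrez identifiers were matched to a RefSeq gene table for 15279 probes, which changed 0 symbols. Of the 527 genes with several probes, the probe with the highest mean over the 27 arrays was kept, leaving 14506 genes. Each tissue was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided) over its 9 arrays with a mean per group and 6 residual degrees of freedom, and 4 contrasts were drawn: the mean of both MCAO groups minus sham, model minus sham, vehicle minus sham and vehicle minus model. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05, with no limit on fold. A difference of effects between tissues was tested in a fit of all 27 arrays with a mean per tissue and group and a single variance per gene for all tissues.

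The named genes followed a rule. For the MCAO contrast they are the 8 largest rises and 8 largest falls among called genes whose sham arrays do not overlap the MCAO arrays; for the other contrasts, the 5 largest each way among called genes whose groups do not overlap; and for each called list, up to 4 members with the smallest p. Where nothing was called, the 3 genes with the smallest p are given. Predicted genes are counted but not named, and genes outside the rule are marked in the text. The rule, the groups, the tests of these comparisons, 40 gene lists of processes and cell types and the alternatives were fixed before the data were examined, except for 1 alternative that leaves out a pair of brain arrays. The tests of explanations and the counts of other splits of the arrays were not part of this. Of 646 list symbols 566 were measured, 13 of them through a synonym. Lists were tested with camera at its preset correlation of 0.01 between genes, adjusted over the 40 lists within a contrast, then again with a correlation estimated from the residuals and with fry, which tests whether the genes of a list move one way on balance. The preset correlation is low for co-regulated genes: camera called between 7 and 20 lists per contrast with it and 0 with the estimated correlation. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

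Alternatives changed a single choice at a time: the arrays in the fit (all 27, or a fit of 2 groups that gives both MCAO groups 1 mean), quantile normalization or median centring within the tissue, a filter at the 40th percentile of mean expression, the mean of all probes of a gene, all probes unfiltered, a variance trend with a robust prior, array weights, a block on replicate number or rat, an adjusted p under 0.10, a fold of at least 2, and leaving out each array. Comparisons that share sham or model arrays were set against 1000 simulated draws without effects. Other splits of the arrays were counted for each comparison, 100 of 840 for the MCAO contrast and all 10 for the rest. The pipeline was tested on simulated data of the same size: between 71.6% and 100% of genes changed by 1 log2 unit were called and 97% to 100% of those changed by 2, with 1 to 12 false calls per comparison, but 5.97% to 55.2% of those changed by 0.5. For differences of effects these shares were 67.2% to 86.6%, 98.5% to 100% and 2.99% to 19.4%, with 6 to 24 false calls. The simulated noise was independent between genes and arrays, so these numbers leave out any structure that arrays share. Other splits of the real arrays gave up to 355 genes in spleen and up to 885 for a difference of effects.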

Results

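Gene expression was measured on 27 arrays from 9 Sprague Dawley rats, with 1 array each for the brain, the white blood cells and the spleen of every rat. Brain and spleen were used as whole homogenates and the white cells had been separated from whole blood, so each value is an average over the cells of the sample. Tissues were taken at 6 h. In each tissue 3 arrays came from sham-operated rats, 3 from rats labelled model and 3 from rats labelled vehicle. Per the treatment protocol every group except sham underwent middle cerebral artery occlusion (MCAO), an operation that blocks a main artery of the brain and serves as a model of ischaemic stroke. The protocol lists a vehicle control group and a group given YJ at 25 mg/kg, YJ being the Yiqi Jiedu formulae of the series title. The samples are instead titled model and vehicle. Their description codes begin with M and D, letters that the labels do not explain. Which of these received YJ is not settled by the labels. They are called model-labelled and vehicle-labelled here, and a difference between them cannot be read as an effect of YJ or of its vehicle. The deposited values ran from 1.53 to 13.49 and were read as log2 intensities. Replicate arrays correlated across genes with r from 0.968 to 0.995. The number of arrays, 3 per group, limits the precision. Differences are given on the log2 scale with the standard error of the limma fit, and group values as mean ± SD of the 3 arrays. A gene rose or fell where its adjusted p was under 0.05 among the 14506 genes tested.

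The first brain comparison set the mean of both MCAO groups against sham at 6 h. Per the protocol a group with MCAO was given YJ, so this difference includes part of any effect of YJ. The same holds in every tissue for differences given as those after MCAO or of MCAO, which cannot be read as effects of the operation alone. Among genes whose arrays did not overlap, the largest rises from the 3 sham brains to the 6 MCAO brains were those of Ccl3, Npas4 and Ccl2, and the largest fall that of Slco1a4. Npas4, a transcription factor switched on by neuronal activity (probe 10727717), rose by 3.86 ± 0.33 (adjusted p = 0.00186), from 5.15 ± 0.79 in sham to 10.38 ± 0.58 in model-labelled and 7.63 ± 0.20 in vehicle-labelled brains. Fos, a subunit of the AP-1 transcription factor, rose by 2.97 ± 0.27 (adjusted p = 0.00203). The chemokines Ccl3 and Ccl2, which attract leukocytes, rose by 4.10 ± 0.61 and 3.45 ± 0.50 (adjusted p = 0.0174 and 0.0153). The small heat shock protein gene Hspb1 rose by 3.06 ± 0.45, Olr1, a receptor for oxidised lipoprotein, by 2.93 ± 0.43, the metalloproteinase inhibitor Timp1 by 2.79 ± 0.33 and the stress-induced transcription factor Atf3 by 2.66 ± 0.42. Among the falls, Slco1a4, an organic anion transporter of the blood-brain barrier, changed by -1.85 ± 0.27 (adjusted p = 0.0153), Sncg, which encodes gamma-synuclein, by -1.48 ± 0.19 and the sulfotransferase gene Sult1a1 by -1.17 ± 0.21. The other named falls, Olfml3, Adh1c, Zc3h6, Lsm8 and Yeats4, lay between -0.91 and -0.60. By the naming rule, all 6 MCAO arrays of each of these 16 genes lay on the same side of all 3 sham arrays. Of the 116 genes called in this comparison 108 had no overlap.

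**Figure D1:**
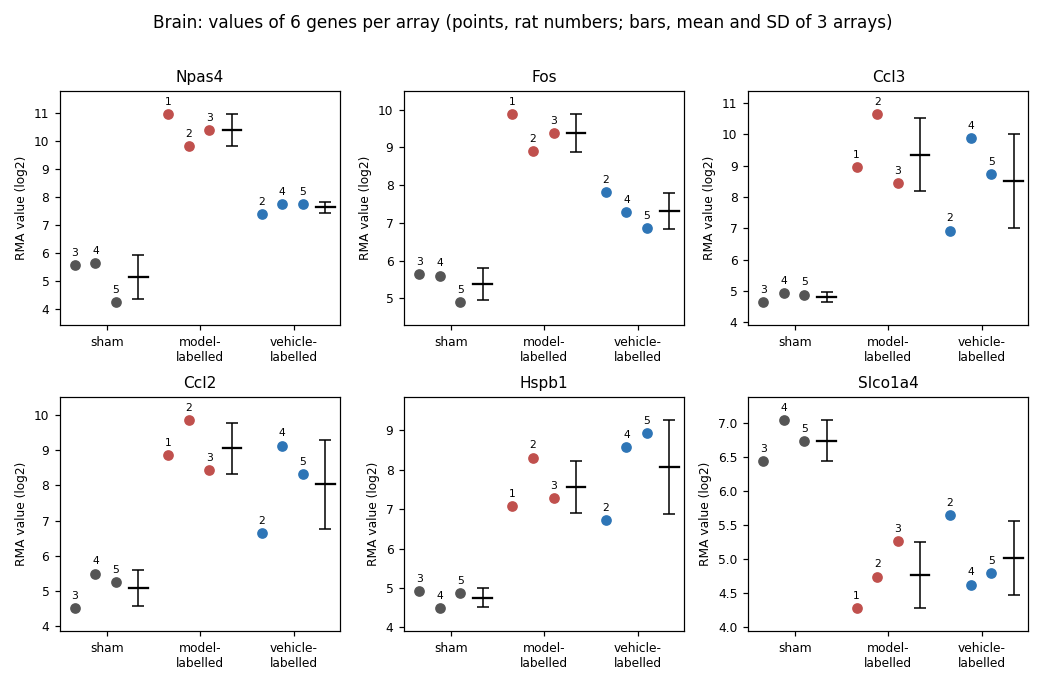
Log2 expression of Npas4, Fos, Ccl3, Ccl2, Hspb1 and Slco1a4 in the 9 brain arrays, with 1 point per array and the mean and SD of each group beside the points. Npas4 stood at 5.15 in sham, 10.38 in model-labelled and 7.63 in vehicle-labelled brains.

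Of 20 measured immediate early genes in the brain, 10 rose over all genes and 18 when adjusted over the list alone, with a median difference of 1.46. Examples were Npas4, Fos, Dusp1 (1.66) and Dusp5 (1.36). The camera test of this list gave adjusted p = 5.42e-26 with the preset correlation between genes and adjusted p = 0.12 with an estimated correlation. Of 16 heat shock and unfolded protein response genes, 7 rose (12 adjusted over the list alone), among them Hspb1, the co-chaperone gene Dnajb1 (1.83), the endoplasmic reticulum chaperone gene Hspa5 (1.14) and Herpud1 (0.96). Camera gave adjusted p = 5.77e-17, and adjusted p = 0.12 with an estimated correlation. Of 22 inflammatory cytokine and chemokine genes, 3 rose over all genes, Ccl3, Ccl2 and Il11 (0.57), and 19 rose when adjusted over the list alone (camera adjusted p = 5.21e-15, and adjusted p = 0.135 with an estimated correlation). Of 17 STAT3 and acute phase targets 7 rose (13 adjusted over the list alone), including Timp1, the oncostatin M receptor gene Osmr (1.73), Pim1 (1.22) and Cebpd (1.20). Camera gave this list adjusted p = 1.66e-16, and adjusted p = 0.109 with an estimated correlation. Of 16 genes of NF-kappaB and Toll-like receptor signalling 3 rose (8 adjusted over the list alone), namely Nfkbia, the NF-kappaB inhibitor (1.64), Cd14 (1.98) and the adhesion molecule gene Icam1 (1.05). For these genes together adjusted p = 3.16e-09, and adjusted p = 0.12 with an estimated correlation.

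Of 18 glucocorticoid-induced genes in the brain, 7 rose and Sult1a1 fell (11 and 2 when adjusted over the list alone). The risers included Errfi1 (1.76), Nfkbia, Cebpd and the kinase gene Sgk1 (1.19). The list gave adjusted p = 9.26e-09, and adjusted p = 0.109 with an estimated correlation. Of 18 hypoxia response genes, 2 rose over all genes, the collagen hydroxylase gene P4ha1 (1.17) and the glucose transporter gene Slc2a1 (0.77). Adjusted over the list alone, 8 rose and 1 fell (adjusted p = 0.000239, and adjusted p = 0.135 with an estimated correlation). Of 14 p53 and growth arrest genes Gadd45b (2.07) and Cdkn1a (1.17) rose, and 6 rose adjusted over the list alone, with adjusted p = 0.000119, and adjusted p = 0.12 with an estimated correlation. None of 12 hypothalamic and thalamic markers passed the test, though their median was -0.88 (adjusted p = 0.00247, and adjusted p = 0.554 with an estimated correlation), and the call was lost without sham 5, where the median was -0.08. On these markers the array of sham rat 5 lay 1.86 above the sham mean and that of vehicle-labelled rat 2 lay at -0.16, while the other 7 lay between -1.25 and -0.65. On cortical markers the arrays of sham rat 5 and vehicle-labelled rat 2 lay at -1.14 and -1.0 and the others between 0.05 and 0.65. In all, limma called 116 genes in this comparison, 108 higher and 8 lower. Without those arrays of sham rat 5 and vehicle-labelled rat 2 it called 318, 111 of the 116 among them. Single arrays mattered as well: the count was 15 without sham 4, 45 without sham 3, 59, 69, 70 and 72 without model 3, vehicle 4, vehicle 5 and model 1, and 245 without vehicle 2. Of the 36 genes named for this comparison that passed, 8 did so whichever single array was left out and 4 in every alternative.

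The next comparisons asked how the model-labelled and the vehicle-labelled brains each differed from sham. In model-labelled brains Npas4 rose by 5.23 ± 0.38 (adjusted p = 0.000634), Ccl3 by 4.52 ± 0.71, Fos by 4.01 ± 0.31 (adjusted p = 0.00065), Ccl2 by 3.96 ± 0.58 and Stc1, which encodes the hormone stanniocalcin 1, by 3.71 ± 0.40 (adjusted p = 0.00257). Slco1a4 fell by 1.98 and Sncg by 1.39, and Zfp3, Gclm and Yeats4 changed by -0.79, -0.78 and -0.74. Of the 20 immediate early genes 15 rose (19 adjusted over the list alone), Junb by 2.43 and Dusp1 by 2.33. The list median was 1.94 (adjusted p = 2.02e-29, and adjusted p = 0.103 with an estimated correlation). Of the 22 cytokine and chemokine genes 5 rose (19 adjusted over the list alone), Il6 by 1.37, Lif by 1.88 and Il11 by 0.98 besides Ccl3 and Ccl2 (adjusted p = 2.37e-16, and adjusted p = 0.128 with an estimated correlation). STAT3 and acute phase genes numbered 8 risers of 17 (12 adjusted over the list alone), Timp1 at 3.64 and Osmr at 2.33 among them. The list had adjusted p = 2.87e-17, and adjusted p = 0.103 with an estimated correlation. Of 13 genes of endothelial adhesion and activation 4 rose (7 adjusted over the list alone), including Plat, the tissue plasminogen activator (1.85), and the anticoagulant receptors Procr (1.16) and Thbd (1.11). The list had adjusted p = 0.123 with an estimated correlation. Among hypoxia response genes 3 rose and 1 fell (7 and 1 adjusted over the list alone), Slc2a1 by 1.17 and the mitophagy receptor Bnip3 by -0.65. The list had adjusted p = 0.00068, and adjusted p = 0.174 with an estimated correlation. In the heat shock list 4 rose (8 adjusted over the list alone; adjusted p = 1.01e-07, and adjusted p = 0.216 with an estimated correlation). None of 14 oligodendrocyte markers (median -0.55) or 12 choroid plexus markers (median 0.54) passed the test. Their lists had adjusted p = 0.0107 and 0.00193, and adjusted p = 0.527 and 0.397 with an estimated correlation. The first lost its call without model 2, sham 3 or sham 5 (medians -0.27, -0.47 and -0.40) and with quantile normalization (-0.49), and the second without model 3 (0.18). None of the genes called here had overlapping groups. By chance 10% of unselected genes would not overlap, but calling a gene already selects groups that lie apart, so this adds no support. In all, 168 genes were called, 157 higher and 11 lower. The count was 325 without sham 5 and vehicle 2 together (162 of the 168 among them), 256 without vehicle 2 alone, and 70, 72, 79 and 87 without model 3, sham 4, model 2 and model 1, while 12 of the 22 named genes that passed did so in every alternative.

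In vehicle-labelled brains limma called 7 genes, all higher than in sham: Dnajb1 (1.89 ± 0.19, adjusted p = 0.0179), Sgk1 (1.48), Nfkbia (1.38), Errfi1 (1.37), P4ha1 (1.36), Herpud1 (1.28) and Nfil3, which stands outside the naming rule and was added after its values were seen. The unadjusted p was under 0.05 for 1354 genes, against 725 expected by chance. Npas4 (2.48, adjusted p = 0.0601), Fos (1.93, 0.0711), Ccl3 (3.69, 0.116) and Hspb1 (3.32, 0.064) did not pass. In the heat shock list Dnajb1 and Herpud1 rose, 15 of 16 rose adjusted over the list alone, and the median was 1.02 (adjusted p = 2.62e-22, and adjusted p = 0.139 with an estimated correlation). Of the glucocorticoid-induced genes 3 rose, with 10 up and 2 down adjusted over the list alone (adjusted p = 3.42e-07, and adjusted p = 0.139 with an estimated correlation). Of the immediate early genes none rose over all genes and 7 adjusted over the list alone (adjusted p = 1.19e-09, and adjusted p = 0.41 with an estimated correlation). The median of the oligodendrocyte markers was 0.58, with adjusted p = 0.00451, and adjusted p = 0.627 with an estimated correlation; the call was lost without vehicle 2 (0.37), without sham 4 (0.41) and without sham 5 and vehicle 2 together (0.48). The count was 224 without sham 5 and vehicle 2 together, 106 without vehicle 2, 33 without sham 5, 3 without model 2, and 0 without any one of vehicle 4, vehicle 5, model 1, model 3, sham 3 and sham 4.

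Compared directly, vehicle-labelled brains had lower values than model-labelled brains for 7 genes, among them Egr2, Lif and Il11, the last pair being cytokines of the IL-6 family. Egr2, an immediate early transcription factor, fell by 2.59 (± 0.32, adjusted p = 0.031), Lif by 1.72 and Il11 by 0.82 (adjusted p = 0.0452 and 0.0351), and Gprc5a, Plscr2 and Phlda1 by 1.64, 1.59 and 1.19 (adjusted p = 0.031 each). Enpp3 also fell but stands outside the naming rule. Rab39a, a small GTPase, rose by 0.96 ± 0.12. Npas4 (-2.75), Junb (-1.75) and Fosl2 (-1.19) had adjusted p = 0.0503. Of the 20 immediate early genes 1 fell over all genes and 18 fell adjusted over the list alone, with a median of -1.36 (adjusted p = 8.92e-19, and adjusted p = 0.368 with an estimated correlation). Of the cytokine and chemokine genes 2 fell (5 adjusted over the list alone; adjusted p = 1.41e-07, and adjusted p = 0.438 with an estimated correlation). Of the STAT3 targets none fell over all genes and 8 adjusted over the list alone (adjusted p = 1.03e-07, and adjusted p = 0.368 with an estimated correlation). The heat shock list stood higher on average instead. Relative to the mean of the 9 brain arrays it lay at 0.15, 0.74 and 0.73 in vehicle-labelled rats 2, 4 and 5. In model-labelled rats 1, 2 and 3 it lay at 0.02, 0.33 and 0.08. Oligodendrocyte markers had a median of 1.17, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 4.83e-06, and adjusted p = 0.438 with an estimated correlation). Choroid plexus markers had a median of -0.68 (adjusted p = 0.00158, and adjusted p = 0.485 with an estimated correlation). This rested on the array of model-labelled rat 3, at 1.66 above the sham mean where the other MCAO arrays lay between -0.10 and 0.52, and without it the median was -0.16 and the call was lost. Oligodendrocyte values against the sham mean were -0.63, -0.90 and 0.13 in model-labelled rats 1, 2 and 3 and 0.91, 0.18 and 0.38 in vehicle-labelled rats 2, 4 and 5. In total 8 genes were called, 1 higher and 7 lower. The count was 63 without sham 5 and vehicle 2 together, 40 without sham 5, 1 without model 1, and 0 without any one of vehicle 2, vehicle 5, model 3, sham 3 and sham 4.

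**Figure D2:**
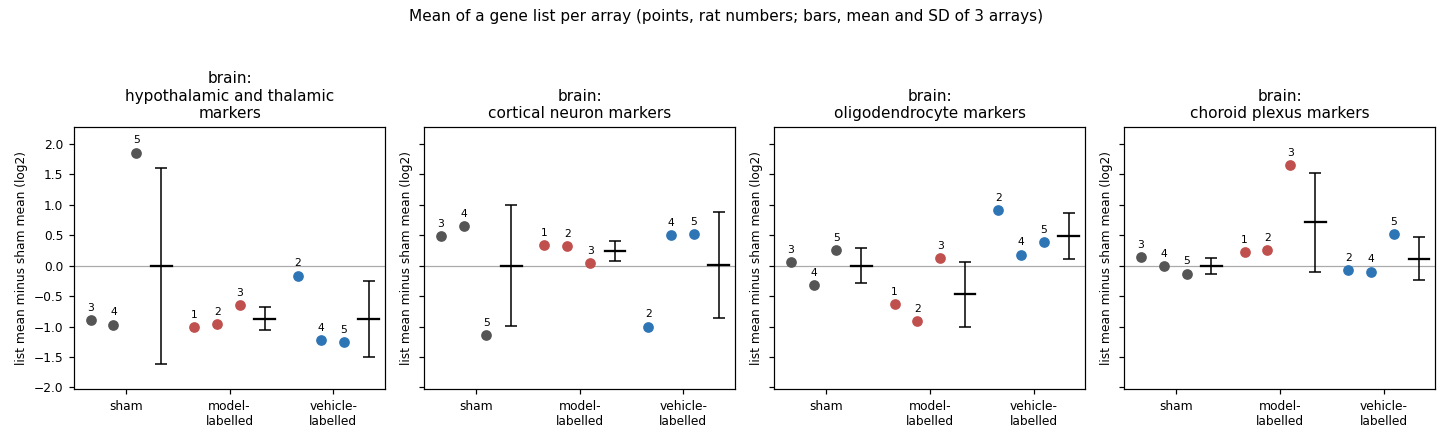
Mean log2 value of the markers of each brain region or cell type in each of the 9 brain arrays, minus the mean of the 3 sham arrays. The array of sham rat 5 stood at 1.86 for hypothalamic and thalamic markers and at -1.14 for cortical markers.

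In white blood cells the largest rises after MCAO among genes whose sham and MCAO arrays did not overlap were those of Hsph1, Bpgm and Alas2, and the largest such fall that of Nrp1. Alas2, the enzyme that starts haem synthesis in erythroid cells (probe 10932912), rose by 1.88 ± 0.17 (adjusted p = 0.000259), as did Bpgm, a red-cell enzyme that sets the oxygen affinity of haemoglobin, by 1.91 ± 0.17. Fech, the last enzyme of haem synthesis, rose by 1.84 (adjusted p = 0.00052), and the blood group gene Rhd, Creg1, Cd52 and Tfdp2 rose by 1.81, 1.81, 1.81 and 1.77. Hsph1, a heat shock protein of the Hsp110 family, rose by 2.05 ± 0.27 (adjusted p = 0.00217). Nrp1, a co-receptor for growth factors and semaphorins, fell by 1.27 (± 0.22, adjusted p = 0.0112), the cold-inducible RNA-binding protein gene Cirbp by 0.63 (± 0.10, adjusted p = 0.00764), and Serpinb6a, Abcg3, Lpl, Ptms, Il36b and Slc14a1 changed by values from -0.86 to -0.60. Of 12 erythroid and reticulocyte markers 10 rose, over all genes and adjusted over the list alone, with a median of 1.53 (adjusted p = 2.16e-28, and adjusted p = 0.138 with an estimated correlation). Of 16 neutrophil genes 3 rose (9 adjusted over the list alone): the granule protein genes Ngp (2.00) and Lcn2 (1.85) and the G-CSF receptor gene Csf3r (0.78). The list had adjusted p = 5.07e-12, and adjusted p = 0.138 with an estimated correlation. Alas2 averaged 8.68 ± 0.36 in sham, 9.78 ± 0.15 in model-labelled and 11.35 ± 0.35 in vehicle-labelled samples, whereas Lcn2 averaged 5.04 ± 0.28, 5.28 ± 0.41 and 8.49 ± 0.38. Ngp averaged 3.93, 4.29 and 7.57 in the same order. The rises of Ngp and Lcn2 thus came mostly from the vehicle-labelled samples. Those of Bpgm, Alas2, Fech, Rhd, Creg1, Cd52 and Tfdp2 were also larger in the vehicle-labelled than in the model-labelled samples. Fech averaged 7.86, 8.65 and 10.73 in the same order, and Cd52 6.35, 7.02 and 9.29. Hsph1 was high in both MCAO groups, at 6.24, 8.1 and 8.48. Of 16 heat shock genes Hsph1, Hsp90aa1 (1.55) and Hspa8 (0.60) rose, and 7 rose adjusted over the list alone (adjusted p = 3.92e-11, and adjusted p = 0.25 with an estimated correlation). Of 18 hypoxia response genes P4ha1 (1.43) and Egln3 (0.74) rose, and 3 rose adjusted over the list alone (adjusted p = 0.00066, and adjusted p = 0.25 with an estimated correlation). Limma called 135 genes, 119 higher and 16 lower, and for 93 of these the sham and MCAO arrays did not overlap. The count was 58 without sham 3 and 81 without sham 4, and 11 in a fit of 2 groups that gives both MCAO groups 1 mean. Of the 23 named genes that passed, 15 did so whichever array was left out and 3 in every alternative.

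Between model-labelled and sham white cells limma called no gene, with an unadjusted p under 0.05 for 880 genes against 725 expected by chance. The smallest p belonged to the co-chaperone genes Fkbp4 (1.08) and Stip1 (1.49) and to Csf3r (0.84), all with adjusted p = 0.085. Hsph1 (1.86) and Hsp90aa1 (1.43) had adjusted p = 0.085 and Alas2 (1.09) adjusted p = 0.0906. Within their lists 7 of 16 heat shock genes rose adjusted over the list alone (median 0.36), and 7 of 12 erythroid markers rose and 1 fell (median 0.56). Camera gave adjusted p = 4.74e-08 and 4.14e-10, and adjusted p = 0.529 with an estimated correlation for both. The count was 2 without model 2 and 3 without model 3.

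Vehicle-labelled white cells differed from sham in 291 genes, led by Ngp, Lcn2 and Car1. Ngp rose by 3.64 ± 0.23 and Lcn2 by 3.45 ± 0.22 (adjusted p = 3.41e-06 each), both genes of neutrophil secondary granules. The red-cell genes Car1, a carbonic anhydrase, Ahsp, the chaperone of alpha-globin, and Rhd rose by 3.25 ± 0.34, 3.19 and 2.95 (adjusted p = 0.000113, 0.000144 and 3.02e-05). Nrp1 and the orphan nuclear receptor gene Nr4a1 fell by 1.35 and 1.22, and Slc25a23, Abcg3 and Faah changed by -0.96, -0.89 and -0.83. Of the 12 erythroid markers 10 rose (11 adjusted over the list alone), among them Fech (2.88), Hemgn (2.86) and Alas2 (2.66). The list median was 2.41 (adjusted p = 2.82e-31, and adjusted p = 0.115 with an estimated correlation). Of the 16 neutrophil genes 8 rose (10 adjusted over the list alone), including the decoy receptor gene Il1r2 (1.94), S100a9 (1.21) and Camp (0.80). The list had adjusted p = 1.63e-14, and adjusted p = 0.115 with an estimated correlation. Of the heat shock genes 4 rose (7 adjusted over the list alone), Hsph1 by 2.24 (adjusted p = 4.97e-10, and adjusted p = 0.298 with an estimated correlation). Of 19 proliferation genes Rrm2 (1.04), Tyms (0.77) and Ccnb2 (0.73) rose, and 4 rose adjusted over the list alone (adjusted p = 1.32e-05, and adjusted p = 0.309 with an estimated correlation). Of the genes called, 229 were higher and 62 lower, and the count was 162 without vehicle 4. Of the 20 named genes that passed, 15 passed whichever array was left out and 13 in every alternative.

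Set against each other, vehicle-labelled white cells exceeded model-labelled ones most in Ngp, Lcn2 and Car1. Ngp was higher by 3.28 ± 0.23 and Lcn2 by 3.21 (adjusted p = 1.84e-05 each), Car1 by 2.94 (adjusted p = 0.000591), Ahsp by 2.63 and Hemgn by 2.31. Of the erythroid markers 8 rose (11 adjusted over the list alone), Rhd by 2.28, Fech by 2.08 and Alas2 by 1.57 (list median 1.65, adjusted p = 1.76e-25, and adjusted p = 0.278 with an estimated correlation). Of the neutrophil genes 4 rose (6 adjusted over the list alone), S100a9 by 1.16 and Camp by 1.04 (adjusted p = 2.26e-09, and adjusted p = 0.308 with an estimated correlation). The interferon-induced antiviral genes Rsad2 (2.00, adjusted p = 0.000682) and Isg20 (1.41) rose, the 2 called among 21 interferon-stimulated genes, of which 5 rose adjusted over the list alone (list adjusted p = 0.00372, and adjusted p = 0.916 with an estimated correlation). Without model 2 that list lost its call, with a median of 0.04. Of 17 T cell genes Tcf7, a transcription factor of naive T cells, fell by 0.81, and 3 fell adjusted over the list alone (list median -0.40, adjusted p = 3.68e-07, and adjusted p = 0.916 with an estimated correlation). None of 11 B cell markers (median 0.28) or 21 ribosomal protein genes (median -0.15) passed, and their lists had adjusted p = 0.00196 and 0.00191, and adjusted p = 0.916 with an estimated correlation for both. The B cell call was lost without model 3 (0.03) and the ribosomal call without vehicle 4 (-0.11). The proliferation genes Tyms (0.94) and Ccnb2 (0.93) rose, with 5 risers adjusted over the list alone (adjusted p = 3.68e-07, and adjusted p = 0.389 with an estimated correlation). Ceacam1, an adhesion molecule, fell by 2.94 (± 0.60, adjusted p = 0.0252) with an SD of 1.83 among the sham arrays, and Slc25a23, Tmlhe, Entrep3 and the CD40 ligand gene Cd40lg changed by values from -0.93 to -0.81. Here 226 genes were called, 183 higher and 43 lower. The count was 108, 149 and 127 without model 1, model 2 and model 3, and 112 and 113 without vehicle 2 and vehicle 4. Here 13 of the 20 named genes that passed did so whichever array was left out and 11 in every alternative.

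**Figure D3:**
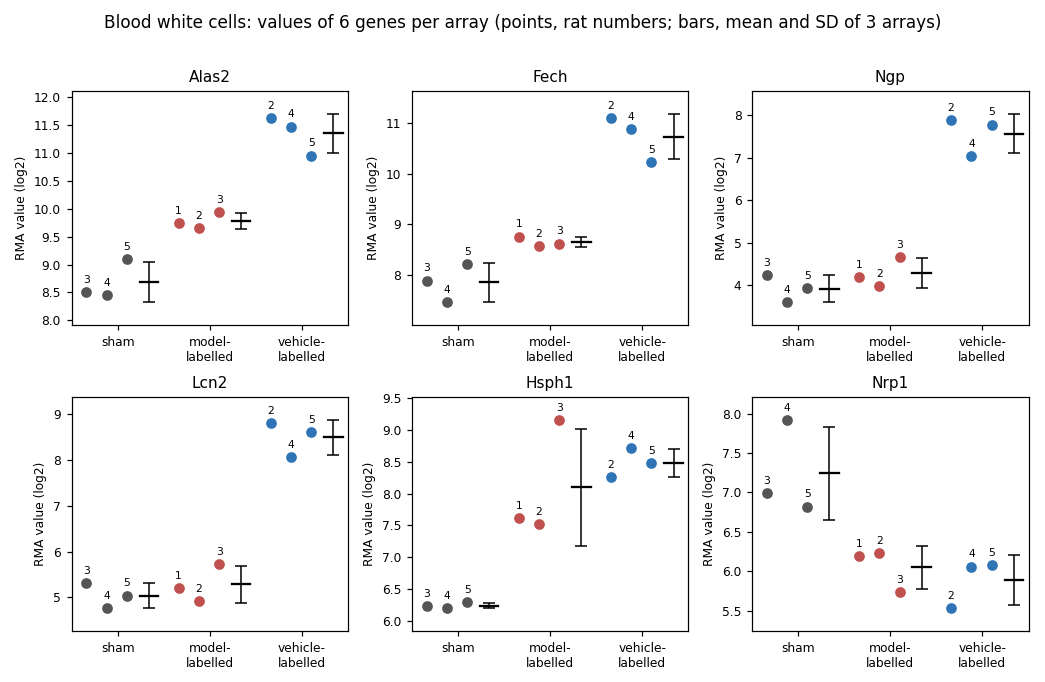
Log2 expression of Alas2, Fech, Ngp, Lcn2, Hsph1 and Nrp1 in the 9 arrays of white blood cells, with 1 point per array and the mean and SD of each group beside the points. Lcn2 stood at 5.04 in sham, 5.28 in model-labelled and 8.49 in vehicle-labelled samples.

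In the spleen 14 genes were called after MCAO, 3 of them in the heat shock list. Hsp90aa1, the inducible form of Hsp90 (probe 10892184), rose by 1.02 ± 0.13 (adjusted p = 0.0149), its co-chaperones Stip1 and Fkbp4 by 1.35 ± 0.18 and 1.35 ± 0.16 (adjusted p = 0.0149 each), Chordc1 and Dnaja1 by 1.32 each, and Cacybp by 1.09. The collagen chaperone gene Serpinh1 rose by 1.36 ± 0.19 and P4ha1, which hydroxylates collagen, by 1.58 ± 0.24 (adjusted p = 0.0157 and 0.0272). Cirbp fell by 0.92 (± 0.12), Cenpu, a centromere protein gene, by 1.16 (± 0.15) and the RNA-binding protein gene Hnrnpd by 0.73, with adjusted p = 0.0149, 0.0149 and 0.0169. Of 16 heat shock genes 3 rose (12 adjusted over the list alone), with Hspa5 at 0.75 and a list median of 0.67 (adjusted p = 1.12e-15, and adjusted p = 0.452 with an estimated correlation). None of 19 proliferation genes passed over all genes, while 7 fell adjusted over the list alone. The median was -0.49 (adjusted p = 2.39e-17, and adjusted p = 0.508 with an estimated correlation). Of the glucocorticoid-induced genes 8 rose adjusted over the list alone and none over all genes (adjusted p = 0.000312, and adjusted p = 0.508 with an estimated correlation). No interferon-stimulated or erythroid gene passed. The list medians were -0.34 and -0.71 (adjusted p = 3.44e-08 and 6.07e-07, and adjusted p = 0.552 and 0.653 with an estimated correlation). Limma called 14 genes, 11 higher and 3 lower, and 1184 had an unadjusted p under 0.05. The count was 9 without vehicle 2, 28 without vehicle 4, 2 without sham 3, 0 without sham 4 or sham 5, and 3, none of them a riser, after centring each array on its median, where the difference of Fkbp4 was 1.27.

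In model-labelled spleens 6 genes were called against sham: Serpinh1 (1.49), Stip1 (1.38), Fkbp4 (1.33) and the zinc transporter gene Slc39a14 (0.94), each with adjusted p = 0.0417, Hspa5 (0.91, adjusted p = 0.0391) and Cenpu (-1.42, adjusted p = 0.0343). In the heat shock list 1 gene rose over all genes and 9 adjusted over the list alone (adjusted p = 2.22e-11, and adjusted p = 0.434 with an estimated correlation). Of the 19 proliferation genes 14 fell adjusted over the list alone and none over all genes, with a median of -0.70 (adjusted p = 6.96e-23, and adjusted p = 0.434 with an estimated correlation). The 12 erythroid markers, none of which passed, had a median of -0.87 (adjusted p = 3.91e-08, and adjusted p = 0.493 with an estimated correlation). The unadjusted p was under 0.05 for 1378 genes. The count was 21 without vehicle 5, 12 without vehicle 4, 1 without model 2, and 0 without any one of vehicle 2, model 1, model 3, sham 4 and sham 5. It was 2, none of them a riser, after centring each array on its median, and 0 without dim genes or with all probes.

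In vehicle-labelled spleens 7 genes were called, 6 higher and 1 lower: Dnaja1 rose by 1.57 and Chordc1 by 1.56 (adjusted p = 0.0411 and 0.0442), Fkbp4 by 1.36 (adjusted p = 0.023), Cacybp by 1.32 and Hsp90aa1 by 1.23, and Cirbp fell by 1.05 (adjusted p = 0.0221 for the last 3). The remaining riser, Manf (0.91), stands outside the naming rule and was added after its values were seen. In the heat shock list 2 rose over all genes and 13 adjusted over the list alone (median 0.67, adjusted p = 1.71e-12, and adjusted p = 0.57 with an estimated correlation). Of 14 exocrine pancreas markers, a neighbouring organ, none rose over all genes and 5 rose adjusted over the list alone (median 0.44, adjusted p = 1.05e-07, and adjusted p = 0.57 with an estimated correlation), with the amylase gene Amy2a3 at 1.89. The median expression level of these markers was 4.42 in spleen, under the median of every array and close to the 4.44 in white cells. No interferon-stimulated gene passed. The median was -0.44 (adjusted p = 4.11e-08, and adjusted p = 0.57 with an estimated correlation). The unadjusted p was under 0.05 for 1357 genes. The count was 16 without vehicle 4, 13 without vehicle 5 or model 3, 1 without sham 5, and 0 without any one of vehicle 2, sham 3 and sham 4. It was 1, a fall, after centring each array on its median and 0 with all probes.

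Between vehicle-labelled and model-labelled spleens limma called no gene, and 1872 genes had an unadjusted p under 0.05 against 725 expected. The smallest p belonged to Ramp2 (-0.91) and Shroom3 (-0.88), with adjusted p = 0.156, and to Irf2bpl (-0.93), with adjusted p = 0.166. The list with the smallest p was that of exocrine pancreas markers, a neighbouring organ. All 14 were higher, none passed over all genes and 3 rose adjusted over the list alone, with a median of 0.35 (adjusted p = 1.32e-06, and adjusted p = 0.626 with an estimated correlation). The median expression level of this list was 4.42 in spleen, 4.44 in white cells and 4.28 in brain, under the median of every array. Of 10 adipocyte markers none passed over all genes and 1 rose adjusted over the list alone (median 0.15, adjusted p = 0.0312, and adjusted p = 0.626 with an estimated correlation), a call lost without vehicle 4 (0.09) or model 2 (0.28). No T cell, B cell, complement or proliferation gene passed over all genes. Adjusted over the list alone, 2 of 11 B cell genes and 3 of 10 complement genes fell and 3 proliferation genes rose; the medians were -0.56, -0.40 and 0.37, and that of the T cell genes was -0.52. Camera gave adjusted p = 0.000122, 0.000238, 7.68e-06 and 3.16e-05 in that order, and adjusted p = 0.626 with an estimated correlation for each. The count was 317 without vehicle 5 and 2 without sham 5.

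**Figure D4:**
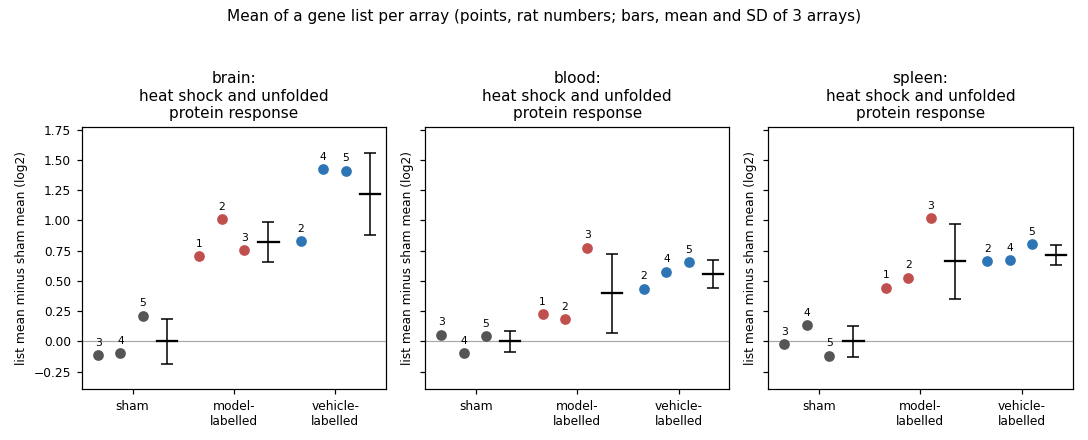
Mean log2 value of the 16 heat shock and unfolded protein response genes in each of the 27 arrays, minus the sham mean of the tissue. The 6 MCAO arrays stood between 0.70 and 1.42 in brain, 0.18 and 0.78 in white blood cells and 0.44 and 1.02 in spleen, above every sham array of the same tissue.

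Whether the tissues answered MCAO differently was tested as the difference between their effects in a single limma fit of the 27 arrays. This fit gives each gene a single spread for all 3 tissues. For the contrasts within brain it called more genes than the fit of the brain arrays alone. Counts and list tests that involve brain thus depend on this pooling. Between brain and white cells the MCAO effect differed for 130 genes, 104 of them with the higher value in brain; between brain and spleen for 93, and between white cells and spleen for 58. Without single rats these counts ranged from 85 (sham 3) to 215 (vehicle 2), from 39 (sham 4) to 133 and from 0 (sham 4) to 78. The effect on the immediate early genes was higher in brain than in white cells by a median of 1.34 and than in spleen by 1.46. Camera gave adjusted p = 6.05e-30 and 2.86e-39, and adjusted p = 0.0181 and 0.00228 with an estimated correlation. In white cells this list did not rise: its median was -0.03, and over all genes 0 rose and 1 fell. The erythroid markers differed between white cells and spleen by a median of 2.35 (adjusted p = 7.83e-29, and adjusted p = 0.0192 with an estimated correlation). The heat shock genes differed by a median of 0.47 between brain and white cells (adjusted p = 0.00829, and adjusted p = 0.655 with an estimated correlation) and of 0.17 between brain and spleen (adjusted p = 0.0239, and adjusted p = 0.536 with an estimated correlation). For vehicle-labelled against model-labelled rats the effects differed for 56 genes between brain and white cells, 87 between brain and spleen and 4 between white cells and spleen; with the rat as a random block, the counts were 114, 160 and 8.

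Model-labelled and vehicle-labelled groups were also compared through their effects against the same sham arrays. Across the 14506 genes, which are not independent replicates, the effects correlated with r = 0.573 in brain, 0.495 in white cells and 0.456 in spleen, where arrays without any effect but with the shared sham arrays gave 0.496, 0.487 and 0.49 on average in simulation, with 95% ranges from -0.088 to 0.836, 0.198 to 0.709 and 0.14 to 0.746 that hold the observed values. The covariance of these effects in white cells, 0.025, lay above its simulated range of 0.0039 to 0.0233. In brain and spleen it lay within its range. The effects of vehicle against model and of model against sham share the model arrays. In white cells they correlated with r = -0.152, outside a simulated range of -0.701 to -0.209, with a covariance inside its range. In brain and spleen r and covariance of this pair lay inside their ranges. The 3 sham arrays are too few to be divided into separate controls.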

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

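Of the tests reported in this part, those of granule genes in white cells, of another part of the brain and of other splits of the arrays, and the comparison of the label-exchange test with a pooled SD, were chosen only after the result was seen.

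Differences of effects come from the fit of all 27 arrays, in which a gene has a single spread for all 3 tissues. The effect of MCAO differed between brain and white cells for 130 genes and between brain and spleen for 93, of which 104 and 84 had the higher value in brain, and between white cells and spleen for 58, of which 53 were higher in white cells. For these counts 2, 3 and 1 of 100 splits of the arrays gave as many, shares under 0.05, with highest other counts of 181, 885 and 33. The splits with 181 and 885 genes both set the rats sham 5, vehicle 2 and vehicle 4 apart, which points to a structure of the samples. Leaving out a single rat moved the brain and white cell count to between 85 (sham 3) and 215 (vehicle 2), the brain and spleen count to 39 (sham 4) or 58 (model 1), and the white cell and spleen count to 8, 13, 22, 0 and 11 (model 1, model 3, sham 3, sham 4 and sham 5).

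For model-labelled rats against sham, the effect differed between brain and white cells for 155 genes and between brain and spleen for 119 (186 with the rat as a block). Between white cells and spleen limma called 0 genes, with 861 at an unadjusted p under 0.05 (2 called with the rat as a block). For vehicle-labelled rats against sham the counts were 125, 21 and 112 in the same order of tissue pairs, the second being 32 with the rat as a block. For vehicle-labelled against model-labelled rats they were 56, 87 and 4, and 114, 160 and 8 with the rat as a block. These comparisons allow only 10 splits, too few for a share under 0.05. The real split gave the largest count in 8 of the 9, that is 1 of 10 splits was as large, with highest other counts of 0 and 2 for model against sham, 4, 5 and 0 for vehicle against sham and 2, 23 and 1 for vehicle against model. In the remaining comparison, model against sham between white cells and spleen, all 10 splits gave at least the real count of 0, and the highest other was 0. Single rats moved most of these counts by over 1.5 times. For model against sham the brain and white cell count was 85, 95 and 97 without model 1, 2 and 3, and the brain and spleen count 49, 74, 71 and 77 without model 1, model 3, sham 4 and sham 5. For vehicle against sham the brain and white cell count was 75, 37, 24 and 36 without model 1, sham 3, sham 4 and vehicle 4. The brain and spleen count was 11, 8, 3, 36, 69 and 4 without model 1, model 2, sham 4, sham 5, vehicle 2 and vehicle 4, and the white cell and spleen count 19, 69 and 65 without sham 4, sham 5 and vehicle 2. For vehicle against model the brain and white cell count was 10, 32, 11 and 156 without model 1, model 2, vehicle 2 and vehicle 5. The brain and spleen count was 7, 12, 32, 55, 41, 16, 25 and 700 without model 1, model 2, model 3, sham 3, sham 4, vehicle 2, vehicle 4 and vehicle 5. The white cell and spleen count was 0 without model 1, model 3 or vehicle 2, 1 without sham 3 or vehicle 4, 7 without sham 5 and 8 without vehicle 5.

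Lists reported in both tissues of a pair were tested for a difference in 19 cases, and 11 passed; 9 genes were tested in the same way and 0 passed, by limma. The effect on heat shock genes was larger in brain than in white cells by a median of 0.47 for MCAO and 0.55 for the vehicle-labelled group, and larger than in spleen by 0.17 and 0.33. None of these 4 passed with an estimated correlation (adjusted p = 0.655, 0.486, 0.536 and 0.391). Glucocorticoid-induced genes differed between brain and spleen by a median of 0.20 for MCAO (adjusted p = 0.104 with an estimated correlation), and B cell markers between white cells and spleen by 0.87 for vehicle against model (adjusted p = 0.174 with an estimated correlation). Erythroid markers differed between white cells and spleen by 2.35 for MCAO and 1.47 for the model-labelled group (adjusted p = 0.0192 and 0.0715 with an estimated correlation). Neutrophil markers differed after MCAO by a median of -0.18 between brain and white cells, 0.89 between brain and spleen and 1.15 between white cells and spleen (adjusted p = 0.415, 0.0464 and 0.00781 with an estimated correlation).

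After MCAO 7, 3 and 3 of 16 heat shock genes rose in brain, white cells and spleen, and the list was called in all 3 tissues but not with an estimated correlation (adjusted p = 0.12, 0.25 and 0.452), which could come from the operation, from a difference in array brightness, from the brain samples that stand apart or from body temperature. The list median exceeded the median of all genes by 0.65 in brain, 0.37 in white cells and 0.62 in spleen. A shift of all genes left in the values is thus too small to give the rise of the list. This cannot decide on brightness itself, because the values had already been normalized between arrays. Centring each array on its median left no riser called in spleen, though the difference of Fkbp4 changed little. The brain arrays of sham 5 and vehicle 2 are argued against as the cause by the list median of 0.87 without them. A higher body temperature of the MCAO rats stays open: Rbm3, a cold-induced gene outside the list, differed by -0.22 in brain with a 95% interval up to 0.31, and by -0.49 (-0.77 to -0.21) and -0.55 (-0.94 to -0.15) in white cells and spleen, so the brain interval spans 0 while the others lie below it, and Cirbp, also cold-induced, fell by 0.63 in white cells and dropped by 0.92 in spleen, with -0.48 (adjusted p = 0.161) in brain. An effect of the ischaemia itself stays open as well.

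In vehicle-labelled against model-labelled white cells 8 of 12 erythroid and 4 of 16 neutrophil genes rose, with adjusted p = 0.278 and 0.308 for the lists with an estimated correlation, which might reflect the treatment, leftover red cells in the preparation or a batch. The granule genes Ngp, Lcn2, Mmp8, Camp and Ltf, which red cells do not carry, had a mean higher by at least 1.31 (1.92, 95% interval 1.31 to 2.52). Red cells by themselves would not give this. These genes were chosen after the result was seen, and Ngp and Lcn2 are the largest rises of this comparison. The test therefore cannot decide whether the preparation left more of other cells together with red cells. For the erythroid markers leftover red cells cannot be told apart from a change in the circulating cells: their median in the spleen was 0.20 against 1.65 in white cells, and the spleen mean had an interval from -1.44 to 2.05. A batch of vehicle-labelled arrays cannot be told apart from the group either. The 183 genes that rose in white cells by a median of 1.13 had a median of 0.14 in brain (139 genes). The 95% interval of their mean difference there was -0.07 to 0.34, against a batch in brain. In spleen the median was 0.27 (176 genes), with an interval of the mean from -0.80 to 1.39. The description codes of the vehicle-labelled arrays also have a form and a letter, D, of their own. A biological difference between the groups stays open, and which group received YJ is not known.

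The brain arrays of sham 5 and vehicle 2 stood apart from the other 7, at -47 and -31.6 on a first component that held 43.5% of the variance. That another part of the brain was sampled goes with the markers: hypothalamic and thalamic markers of both arrays lay at least 0.48 above the highest of the other 7, and cortical markers lay at -1.22 and -1.08 against -0.03 to 0.57 for the others, relative to the mean of 9 arrays. The labels name no brain region or hemisphere, so this remains a hypothesis, and no biological explanation was tested, as no group of the design holds this pair. An exchange of labels between them is argued against by the heat shock list, in which vehicle 2 lay 0.62 above the highest sham array and sham 5 lay 0.49 below the lowest MCAO array, where the SD between arrays of a group was 0.24. The criterion set for this test before was not met in full, since sham 5 (-0.47) lay above sham 3 (-0.80) and sham 4 (-0.78), as an exchange would need.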

How the results depend on the processing

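The alternative without the brain arrays of sham 5 and vehicle 2 was the only one here chosen after the result was seen. In simulated data of this size, with noise independent between genes and arrays, 5.97% to 55.2% of genes changed by 0.5 log2 units were called. Counts below run in the order MCAO, model against sham, vehicle against sham and vehicle against model, and a count is given where it moved by over 1.5 times. Of 181 named gene results 0 reversed and 43 kept their side of the threshold in every alternative; 161 passed as reported. Called lists kept their call in 1224 cases of leaving out an array, lost it in 142 and reversed in 2. The causes were not tested except where fewer arrays or genes explain a count.

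With only the arrays compared in a fit of 2 groups, where MCAO keeps all 9 arrays but the model-labelled and vehicle-labelled arrays share a mean, brain gave 30 (MCAO), 0 (vehicle against sham) and 0 (vehicle against model), white cells 11 (MCAO) and spleen 6 (MCAO), 23 (model against sham) and 1 (vehicle against model). With a single fit of 27 arrays, brain gave 397, 557, 208 and 346, white cells 12 for model against sham and spleen 46, 62, 29 and 107. Array weights gave 637, 573, 369 and 123 in brain, 13 (model against sham) and 555 (vehicle against model) in white cells, and 36 (MCAO) and 123 (model against sham) in spleen; the lowest weights were 0.35 and 0.41 for brain sham 5 and vehicle 2, 0.28 for white cells of sham 3 and 0.35 for spleen vehicle 5. Without brain sham 5 and vehicle 2, brain gave 318, 325, 224 and 63, which included 111, 162, 7 and 8 of the genes called before, and the hypothalamic and thalamic list reversed to 0.08 for model against sham. A fold of at least 2 left 70 for MCAO in brain, 64, 130 and 109 in white cells (MCAO, vehicle against sham, vehicle against model) and 9 for MCAO in spleen. An adjusted p under 0.10 gave 209, 282, 53 and 55 in brain, 16 (model against sham) and 442 (vehicle against sham) in white cells, and 24 (MCAO) and 13 (model against sham) in spleen.

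Quantile normalization gave 11 (vehicle against sham) and 13 (vehicle against model) in brain and 4 genes and 9 lists for vehicle against sham in spleen. Median centring gave 14 for vehicle against sham in brain and 3, 2 and 1 in spleen for the comparisons with sham, where no riser was left. The filter on dim genes gave 21 for vehicle against sham in brain and 0 for model against sham in spleen. The trend with a robust prior gave 20 for vehicle against sham in brain and 14 for model against sham in spleen. All probes gave 38 for vehicle against model in brain and 0 for both model and vehicle against sham in spleen. The rat block gave 114 for vehicle against model between brain and white cells, 186, 32 and 160 between brain and spleen (model against sham, vehicle against sham, vehicle against model), and 2 and 8 between white cells and spleen (model against sham, vehicle against model). A block on replicate number had correlations of -0.086, -0.086 and 0.101 in brain, white cells and spleen and moved no count past 1.5 times. With an estimated correlation all 12 list counts were 0. Fry gave 12, 13, 2 and 0 lists in brain, 1, 0, 2 and 1 in white cells and 0 in all 4 spleen comparisons.

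Leaving out each array in turn gave 15 to 245, 70 to 256, 0 to 106 and 0 to 40 genes in brain, 58 to 174, 0 to 3, 162 to 350 and 108 to 273 in white cells, and 0 to 28, 0 to 21, 0 to 16 and 0 to 317 in spleen. Differences of effects ranged over 85 to 215, 85 to 188, 24 to 139 and 10 to 156 between brain and white cells, 39 to 133, 49 to 159, 3 to 69 and 7 to 700 between brain and spleen, and 0 to 78, 0 to 0, 19 to 131 and 0 to 8 between white cells and spleen. Lists reversed in 2 cases: hypothalamic and thalamic markers for model against sham in brain (-1.50 to 0.08, reversed without sham 5) and erythroid markers for vehicle against sham in spleen (-1.02 to 0.03, reversed without vehicle 5). A group left with 2 arrays is assumed to vary like the others in the pooled fit.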

Other observations

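All tests of other splits in this part were chosen only after the result was seen.

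Several lists not described above were also called by camera in brain. None of 16 neutrophil markers passed over all genes after MCAO, and their median was 0.19 (adjusted p = 0.0021, and adjusted p = 0.129 with an estimated correlation); Lcn2, a secreted iron-carrier protein, was at 0.92 and the calcium-binding S100a9 at 0.70. Of 16 reactive astrocyte genes 4 rose (8 adjusted over the list alone), among them Cp, which encodes ceruloplasmin, by 0.94 and the pentraxin gene Ptx3 by 1.12 (adjusted p = 3.8e-08, and adjusted p = 0.147 with an estimated correlation). Ribosomal protein genes (21 measured, median -0.19, adjusted p = 1.77e-05) and genes of the mitochondrial respiratory chain (17 measured, median -0.08, adjusted p = 0.0165) had adjusted p = 0.527 and 0.554 with an estimated correlation. The ribosomal call was lost without sham 5 (median -0.05) or without sham 5 and vehicle 2 together (-0.09), and the mitochondrial call without sham 4, sham 5 or vehicle 5 (-0.08, -0.07 and -0.04), without sham 5 and vehicle 2 together (-0.06) and with quantile normalization (-0.04). Hmox1, which encodes the haem-degrading enzyme, was at 2.49 in brain after MCAO with adjusted p = 0.0514.

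In spleen, neutrophil markers had a median of -0.51 after MCAO (adjusted p = 9.76e-07, and adjusted p = 0.508 with an estimated correlation) and 8 plasma cell markers one of 0.24 (adjusted p = 0.00399, and adjusted p = 0.653 with an estimated correlation), a call lost without vehicle 5 (0.23). In white cells 11 B cell markers had a median of 0.32 in the vehicle-labelled group against sham, with 0 genes past the test over all genes by limma and 1 adjusted over the list alone (adjusted p = 3e-05, and adjusted p = 0.447 with an estimated correlation). The choroid plexus markers of the brain array of model-labelled rat 3 lay 1.66 above the sham mean.

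Other splits of the arrays were counted for every comparison within a tissue. For MCAO against sham 100 of the 840 splits were drawn. In brain 1 of them, the real one, gave 116 genes (highest other 18), and in white cells 1 gave 135 (highest other 11). These shares are under 0.05 for the division into 3 groups as fitted. Both highest others kept the 3 sham arrays together and only divided the MCAO arrays anew, so the gap to the real counts also rests on the division into model-labelled and vehicle-labelled arrays. With both MCAO groups given 1 mean the counts were 30 and 11, and with the groups apart the brain count was 15 without sham 4. The fit with 1 mean was not split, so chance is not excluded for a difference between sham and MCAO rats that leaves this division aside. In spleen 4 gave 14 or more, a share under 0.05, but the real count was 0 without sham 4 or sham 5, and chance is not taken to be excluded for it. The highest other count in spleen was 355, with model 1, model 3 and vehicle 5 in the place of sham, which points to a structure of the spleen samples. The numbers of called lists are another matter: 18, 23 and 46 of 100 splits gave as many as the real 15, 9 and 12, with highest others of 23, 14 and 24, so chance cannot be excluded for them.

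The remaining comparisons allow 10 splits each, too few for a share under 0.05. In brain the real split alone, 1 of 10, gave 168, 7 and 8 genes for model against sham, vehicle against sham and vehicle against model, with highest others of 0, 0 and 1; for lists 1, 2 and 2 splits gave as many as the real 20, 12 and 14, with highest others of 14, 13 and 14. In white cells 10, 1 and 1 splits gave as many genes as the real 0, 291 and 226, with a highest other of 1 in each, and 6, 3 and 6 gave as many lists as the real 7, 9 and 8, with highest others of 10, 9 and 10. In spleen 1, 1 and 10 splits gave as many genes as the real 6, 7 and 0, with highest others of 0, 2 and 187, the last setting model 1, model 3 and vehicle 5 apart, and 3, 3 and 3 gave as many lists as the real 15, 16 and 15, with highest others of 21, 21 and 19.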
